A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

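Gene expression was measured in budding yeast on 6 single-colour oligonucleotide arrays with 9335 probe sets. There were 3 arrays of a wild-type strain and 3 arrays of a strain with an altered histone H2B. Per the labels, cells were grown in rich medium to mid-log phase, total RNA was extracted with hot acid phenol, and biotin-labelled RNA was hybridised. The deposited values are an intensity per probe set on a linear scale, made by the authors with MAS5 per the submitters' processing notes. The version of that software, its settings and its detection calls are not given in the sources used here. The 2% trimmed mean of each deposited column lay between 125.1 and 125.2, so the columns already shared a scale and were used as deposited.

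Of the 9335 probe sets, 60 controls were left out. Among the other 9275, the platform's gene table gave 1 gene for 6504 probe sets, several for 328 and none for 2443. Only probe sets with 1 gene entered, and symbols were updated through the gene identifier in the R64 reference table, in which all 5656 genes were found. A gene with several probe sets was represented by the brightest. An offset of 2.7, the 10th percentile of all non-control values, was added before taking log2, so fold changes of dim genes are understated. Genes with a mean log2 value below the 20th percentile were left out (1131 genes), and 4525 genes were tested. For 231 of these, the probe set has a name that marks possible signal from related sequences.

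Mutant and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend on mean level), two-sided, with Benjamini-Hochberg adjustment over the 4525 genes and a threshold of 0.05. The fit chosen before the data were examined held the group only, and a fit with the replicate number as a block was fixed at the same time as an alternative to it. The labels number the replicates 1 to 3 in both groups, and whether these numbers pair the arrays was checked before calls were compared. Deviations from the group means of same-numbered arrays correlated across genes at 0.52, 0.59 and 0.86 for replicates 1, 2 and 3. The numbers were therefore taken to pair the arrays. Wild-type array 1 correlated at 0.51 with mutant array 2, and wild-type array 2 at 0.65 with mutant array 1. These values do not show that replicates 1 and 2 are paired by number, so that part of the block rests on the labels. The label of wild-type array 3 names it as the wild type for other H2B mutants too, while those of wild-type arrays 1 and 2 name this mutant alone. Most of this pairing separates replicate 3 of both groups from the others: arrays 3 of opposite groups correlated at 0.86 and array 3 against arrays 1 and 2 of the other group at -0.61 to -0.75. Spiked hybridisation controls averaged 96.6 and 89.9 on wild-type and mutant array 3, against 323.7 to 479.8 on the other 4 arrays. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of all values.

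The gene lists were fixed at that time too. Of 33 lists, 29 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01, adjusted over the 29. The same test was run with an estimated correlation. Subtelomeric genes were the 10 outermost open reading frames of each chromosome arm by systematic name, compared with other genes by Fisher's exact test, two-sided, on the share of genes called higher. The share called lower was tested in the same way after the data were seen. Camera was also run over the 16 chromosomes. Named genes followed a rule fixed in advance: the histone genes, the 12 largest rises and 12 largest falls among passing genes whose groups did not overlap, up to 4 passing members of each list with the smallest p (or the 2 smallest where none passed), and up to 4 passing subtelomeric genes. The rule was applied to both fits, the fit with the block having been added to it after the data were seen. Other genes named in the text were chosen after their values were seen.

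The alternatives were quantile normalization, scaling to a common median, a smaller and a larger offset, other filters on dim genes, other variance priors, the mean of a gene's probe sets, only probe sets without a mark of shared sequence, all probe sets, other subtelomeric widths, a rotation test of the lists (fry) and leaving out each array. After the data were seen, a batch block for replicate 3, replicates 1 and 2 alone, and these alternatives within the fit with the replicate block were added. The steps were tested on simulated data: 10 sets of 4525 genes with the real means, replicate deviations and spread, each with 200 changed genes and 1 shifted list. The pairing and the spread of the fit with the block were built into these sets, so they favour that fit and do not test whether the real arrays are paired. With the replicate block, 90.75% of genes changed 1.5-fold, 99.1% of those changed 2-fold and 99.2% of those changed 4-fold were recovered, and 4.52% of calls were false. With the group only, the shares were 0.597%, 27.8% and 90.45%. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.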

Results

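The data comprise 6 arrays of yeast RNA, 3 from a wild-type strain and 3 from a strain whose histone H2B is altered at residues 3 to 32. In work on such strains this notation stands for a deletion of that stretch, which lies in the amino-terminal tail of H2B. The comparison asks which genes depend on this part of the tail in growing cells. Median signals were 28.7 to 31 on the 4 arrays of replicates 1 and 2, and 40 and 40.5 on the arrays of replicate 3. The fit with the group only, the one chosen before the data were examined, passed 1 gene, HTB1. For all other genes "rose" and "fell" refer to the fit with the replicate block at an adjusted threshold of 0.05, and none of these calls was made without the block.

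HTB1, which encodes H2B, was the most changed gene. Its signal was 1234 ± 122 (SD, n = 3) in wild type and 16.9 ± 2.21 (n = 3) in the mutant, a log2 change of -5.98. Its limma adjusted p was 2.17e-06 with the group only and 2e-14 with the replicate block. HTB1 was lower in 3 of 3 mutant arrays, which lay between 15.2 and 19.4 against 1138 to 1372 in wild type. The position of its probe set within the gene is not given in the sources used here, and a probe set inside the altered part would not measure the rest of the transcript. HTB2, the other H2B gene, was near background in both groups (4.47 ± 0.902 and 4.3 ± 1.49, n = 3) and was left out as dim. The other measured histone genes did not pass: HTZ1, the H2A variant, had a log2 change of -0.22 (adjusted p = 0.271), HHO1, the linker histone, -0.25 (adjusted p = 0.271), and CSE4, the centromeric H3 variant, 0.14 (adjusted p = 0.697). Probe sets for the other core histones matched several genes and were not used.

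**Figure D1:**
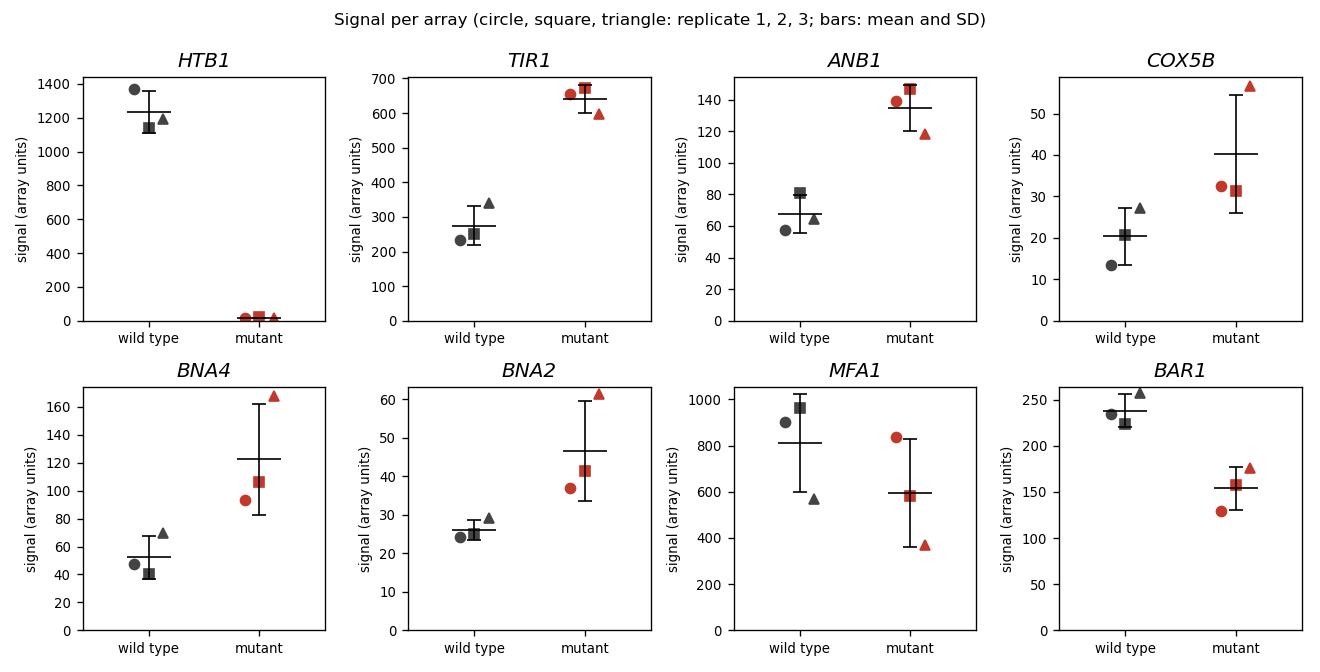
Signal per array in array units (vertical axes, linear, from 0) for 8 genes in wild type (grey) and mutant (red), with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean and SD of 3 arrays. HTB1 is at 15.2 to 19.4 in the mutant, TIR1, ANB1, COX5B, BNA4 and BNA2 lie higher in all mutant arrays, BAR1 lies lower, and MFA1 overlaps between the groups.

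Beyond HTB1, the fit with the replicate block gave higher signals in the mutant for TIR1, ANB1 and several genes of NAD synthesis, and lower signals for genes of the respiratory chain and genes specific to the a mating type. Both of these list shifts passed camera with a preset correlation only (adjusted p = 0.383 for each with an estimated correlation) and did not pass fry for movement in 1 direction (adjusted p = 0.123 and 0.134). With the block, 103 of 4525 genes changed, of which 40 rose and 63 fell. This fit left 2 residual degrees of freedom per gene, against 12.5 for the variance prior shared between genes. Its calls therefore lean on that prior. Only 4 genes rose and 1 fell at least 2-fold. The genes that rose at least 2-fold were TIR1, BNA4, COX26 and RDN25-1, a ribosomal RNA gene. TIR1 is a cell wall mannoprotein made at low oxygen and in the cold (275 ± 56.9 against 641 ± 39.5, n = 3, log2 1.23, adjusted p = 9.1e-05). BNA4 is an enzyme of NAD synthesis (log2 1.17, adjusted p = 1e-04). COX26 is a small protein of the respiratory supercomplex (log2 1.11, adjusted p = 0.0029). Its signal was low in both groups (12 ± 1.85 against 29.2 ± 4.2, n = 3).

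The other large rises among genes whose groups did not overlap were smaller. They included ANB1, the form of translation factor eIF5A made at low oxygen (log2 0.97), and COX5B, the low-oxygen form of a cytochrome c oxidase subunit (0.89). Also among them were SNO1 of vitamin B6 synthesis (0.82) and the drug transporter gene QDR2 (0.82). EMA19, which takes part in targeting proteins to mitochondria (0.81), and GDH3, a glutamate dehydrogenase (0.78), followed. COX5B, SNO1, QDR2 and GDH3 had low signals, with wild-type means of 20.4, 16.8, 15.1 and 21.3. Among genes whose groups did not overlap, the largest falls after HTB1 were CDC26, a subunit of the anaphase-promoting complex (log2 -0.89), AAD4, an aryl-alcohol dehydrogenase family gene whose probe set may share signal (-0.76), RAM2, a subunit of protein prenyltransferases (-0.75), YNL134C (-0.72), the phosphatase gene SIT4 (-0.71), FOL3 of folate synthesis (-0.70), ATP11, an assembly factor of the mitochondrial ATP synthase (-0.69), SPC19 of the kinetochore Dam1 complex (-0.64), BAR1 (-0.63), GTT2, a glutathione transferase (-0.62), and PHO87, a phosphate transporter (-0.61). All 103 genes had the same sign in the 3 pairs of same-numbered arrays. They were chosen by a fit on these same differences, so such agreement is largely built into the choice. In 61 of them the groups did not overlap, as in 346 of all tested genes (7.65%). Chance gives 10% for 3 against 3 exchangeable arrays, which these paired arrays are not, so the shares are not directly comparable.

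Without the block limma called 0 genes higher and 1 gene, HTB1, lower. An unadjusted p under 0.05 was found for 113 genes (47 higher, 66 lower). These are 2.5% of the genes tested, fewer than a threshold of 0.05 gives when nothing changes. With the block 781 genes (17.3%) had an unadjusted p under 0.05 (234 higher, 547 lower). TIR1 had an adjusted p of 0.243 without the block. With the arrays of replicate 3 as a batch, 45 genes were higher and 74 lower, and within replicates 1 and 2 alone 17 were higher and 27 lower. The other batch holds 1 array per group, which allows no test. The counts with the replicate block also depended on single pairs: 79 higher and 153 lower without replicate 1, 13 and 17 without replicate 2, and 7 and 6 without replicate 3. The last fit used the same arrays as that within replicates 1 and 2 alone and differed only by the replicate block. Its lower counts therefore do not come from the loss of a pair alone.

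RDN25-1, a gene of the 25S ribosomal RNA, rose from 347 ± 102 to 935 ± 194 (n = 3, log2 1.45, adjusted p = 9.1e-05), and its probe set may share signal. Its log2 difference was 1.57 in replicate 1, 0.88 in replicate 2 and 1.89 in replicate 3, while the 5 tested ribosomal RNA genes had a median log2 difference of 1.36 in replicate 1, 0.32 in replicate 2 and 0.19 in replicate 3. Control probe sets for the same RNA averaged 347, 109 and 38.1 on mutant arrays 1, 2 and 3. On the same-numbered wild-type arrays they averaged 45.2, 73.4 and 27.3.

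Genes of oxidative phosphorylation, which make up the respiratory chain and ATP synthase, were lower as a group. Of 38 tested members 1 rose, 9 fell and 28 did not pass, while 22 fell and 1 rose when adjusted over the list alone. Without the block 0 passed either way. The genes that fell included CYT1, cytochrome c1 (log2 -0.57), RIP1, the Rieske iron-sulfur protein (-0.51), CYC1, the main cytochrome c (727 ± 54.7 against 523 ± 64.3, n = 3, log2 -0.48, adjusted p = 0.0149), and QCR6 of complex III (-0.38). COX5B was the member that rose, and 1 of the 38 had a positive log2 change. The list's median was -0.29 and its mean less that of the other genes was -0.21 (adjusted p = 5.61e-11). The call was lost with an estimated correlation (adjusted p = 0.383 with an estimated correlation). Mitochondrial ribosomal protein genes were lower too: 3 of 66 fell, 0 rose and 63 did not pass, with 6 lower when adjusted over the list alone. The 3 were MRP51, MRP1 and MRP2 of the small subunit (log2 -0.53, -0.41 and -0.46). The list's median was -0.17 (adjusted p = 0.00264, and adjusted p = 0.383 with an estimated correlation). Without the block, the list's mean less that of the other genes turned from -0.10 to 0.01 when wild-type replicate 3 was left out.

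Genes of NAD and biotin synthesis included 6 of 17 that rose, with 0 falls and 11 that did not pass, and 7 higher and 1 lower when adjusted over the list alone. The 6 lie in NAD synthesis from tryptophan or in uptake of nicotinic acid: BNA4, kynurenine monooxygenase (52.3 ± 15.3 against 122 ± 39.9, n = 3), BNA1 (log2 0.77), BNA2, the first enzyme of the pathway (0.75), BNA5 (0.66, named after its value was seen), BNA6 (0.52) and TNA1, the nicotinic acid transporter (0.47). The list's mean was 0.19 and its test was up (adjusted p = 0.00129, and adjusted p = 0.383 with an estimated correlation), while its median was -0.05, so median and mean differed in sign. In the vitamin B1 and B6 list 2 of 14 rose, 0 fell and 12 did not pass, and 2 passed when adjusted over the list alone. These were SNO1 and SNZ1 (log2 0.65), which act together in making vitamin B6 (list median 0.09, adjusted p = 0.0128, and adjusted p = 0.456 with an estimated correlation). Among amino acid synthesis genes 3 of 56 rose, 0 fell and 53 did not pass, and 3 passed when adjusted over the list alone: HIS4 of histidine synthesis (log2 0.73), GDH3 and ARG7 of arginine synthesis (0.57). The list's median was 0.04 (adjusted p = 0.00704, and adjusted p = 0.383 with an estimated correlation).

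Genes specific to the a mating type fell in 3 of 6 cases, with 0 rises and 3 that did not pass, and 5 were lower when adjusted over the list alone. They were BAR1, the protease that degrades alpha factor (238 ± 17.6 against 154 ± 23.3, n = 3, adjusted p = 0.00497), AGA2 of the a-agglutinin (log2 -0.51) and MFA1, a gene of the a-factor pheromone whose probe set may share signal (-0.48). The list's median was -0.41 (adjusted p = 0.00168, and adjusted p = 0.383 with an estimated correlation). In the pheromone response list 1 of 19 fell, SST2, which desensitises cells to pheromone (log2 -0.60), and 4 were lower when adjusted over the list alone, but the list was not shifted (adjusted p = 0.116). The list drawn up for the alpha mating type had 2 tested genes and was not tested. SAG1 had a log2 change of -0.26 and HMRA1 of 0.13, and neither passed. HMRA1 is a copy of an a-type gene, not an alpha-specific one, and its probe set may share signal.

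Further lists were shifted with few or no members that passed. Phosphate genes were higher with 0 of 16 passing, 1 when adjusted over the list alone (median 0.08, adjusted p = 0.00704, and adjusted p = 0.456 with an estimated correlation), among them PHO89 (log2 0.43) and the phosphatase gene PHO5 (0.29). Iron genes were higher with 0 of 21 passing and 0 when adjusted over the list alone (median 0.10, adjusted p = 0.0145, and adjusted p = 0.383 with an estimated correlation). Sterol synthesis genes were higher with 0 of 26 passing and 0 when adjusted over the list alone (median 0.03, adjusted p = 0.0145, and adjusted p = 0.535 with an estimated correlation). Genes often deleted or used as markers in laboratory strains were higher with 0 of 9 passing and 2 when adjusted over the list alone (median 0.12, adjusted p = 0.0185, and adjusted p = 0.535 with an estimated correlation), with TRP1 at 0.42 and LEU2 at 0.33. The strain background, and how the H2B gene is carried in either strain, are not given in the sources used here, which limits what the signals of the marker genes and of HTB1 and HTB2 stand for. G1/S cell cycle genes were lower with 0 of 38 passing and 0 when adjusted over the list alone (median -0.16, adjusted p = 0.0145, and adjusted p = 0.383 with an estimated correlation). Sulfur and methionine genes were lower with 1 of 21 falling, MET6, methionine synthase (log2 -0.51), and 2 when adjusted over the list alone (median -0.15, adjusted p = 0.021, and adjusted p = 0.456 with an estimated correlation). Cell wall integrity genes were lower (median -0.17, adjusted p = 0.0227, and adjusted p = 0.383 with an estimated correlation), although the 1 member of 23 that passed, the glucan synthase gene GSC2, rose (log2 0.66), with 1 higher and 1 lower when adjusted over the list alone. With scaling to a common median, the iron, sterol, marker, G1/S, sulfur and cell wall lists no longer passed.

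**Figure D2:**
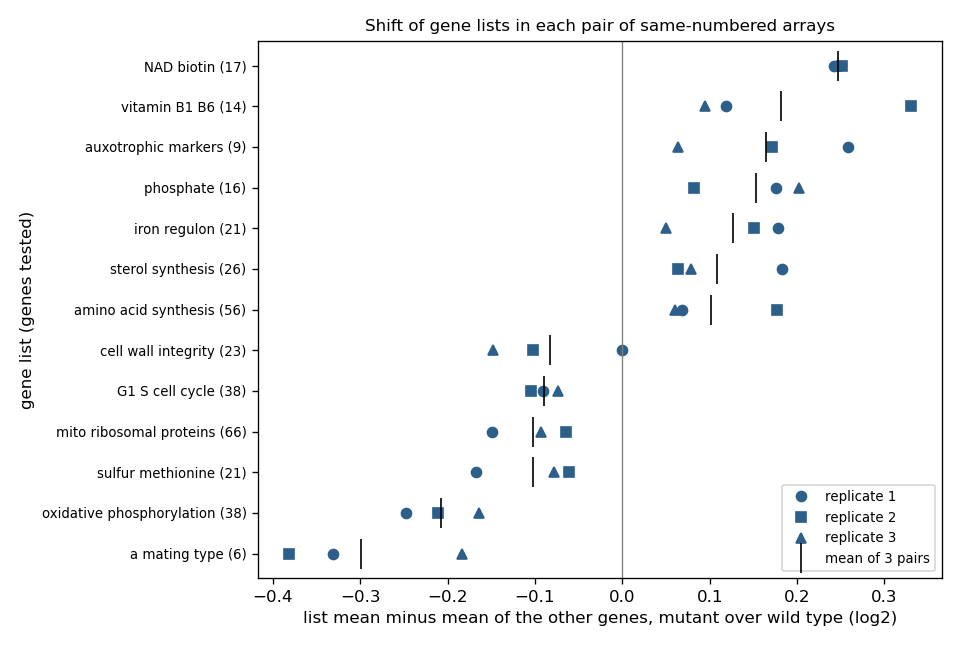
Mean log2 change of each gene list less that of the other genes (horizontal axis), per pair of same-numbered arrays (circles, squares and triangles for replicates 1, 2 and 3) and over the 3 pairs (black ticks), for the 13 lists that passed with the replicate block and a preset correlation; the number of tested genes is in brackets. The NAD and biotin list lies at 0.24 to 0.25 and the oxidative phosphorylation list at -0.25 to -0.16 in the 3 pairs.

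The list of cell wall mannoproteins made at low oxygen was not shifted (adjusted p = 0.671): TIR1 and TIR3 (log2 0.42) rose, 0 fell and 11 of 13 did not pass, with 2 higher and 3 lower when adjusted over the list alone. Among hexose transport genes 1 of 8 fell, also 1 when adjusted over the list alone: HXT1, a low-affinity glucose transporter (841 ± 104 against 564 ± 39.3, n = 3, log2 -0.57). The list was not shifted (adjusted p = 0.671), nor were glucose-repressed genes (0 of 10 passing, 1 lower when adjusted over the list alone, adjusted p = 0.714). In the drug transport list QDR2 rose and FLR1 fell (log2 -0.98), with 1 higher and 3 lower of 21 when adjusted over the list alone (adjusted p = 0.506). HUG1, a DNA damage-induced gene, rose (log2 0.55) and was the 1 gene of 17 in its list that passed, also when adjusted over the list alone (adjusted p = 0.678). HSP31 fell (log2 -0.54) in the stress list, with 26 of 27 not passing and 3 lower when adjusted over the list alone (adjusted p = 0.806). RPL9B, whose probe set may share signal, fell (log2 -0.67) among 81 ribosomal protein genes, also 1 when adjusted over the list alone (adjusted p = 0.672). AAD4 fell among 11 subtelomeric family genes, also 1 when adjusted over the list alone (adjusted p = 0.714). Lists with 0 passing members and no shift were chromatin and silencing (40 genes, adjusted p = 0.806), ribosome biogenesis (79 genes, adjusted p = 0.554), G2/M cell cycle (34 genes, adjusted p = 0.153), proteasome (35 genes, adjusted p = 0.506), glycolysis (18 genes, adjusted p = 0.118), reserve carbohydrates (16 genes, adjusted p = 0.716) and zinc (13 genes, adjusted p = 0.827). Adjusted over the list alone, 0 passed in these except in the zinc list, with 1 higher and 1 lower. For the reserve carbohydrate, stress, ribosome biogenesis, zinc, low-oxygen mannoprotein, subtelomeric family, DNA damage and chromatin lists, median and mean were below 0 while the test, which compares with the other genes, pointed up, and glucose-repressed genes had a positive median and a negative mean.

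The galactose list had 3 tested genes and the sporulation list 4, too few for a list test. GAL80, the repressor of galactose genes, had a log2 change of -0.30 (adjusted p = 0.14), GCY1 of 0.17 (adjusted p = 0.534), SPS19 of 0.44 (adjusted p = 0.206) and SGA1 of 0.44 (adjusted p = 0.137).

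In total 13 of 29 lists were shifted in both fits, 7 up and 6 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.309 with the group only and 0.383 with the block. A rotation test of each list's own genes, fry, passed 0 lists with the block when it asked whether genes move on balance 1 way (lowest adjusted p = 0.123). Asked whether genes changed in either direction, it passed 16 of the 29 lists with the block (lowest adjusted p = 0.00514) and 0 without it (lowest adjusted p = 0.114), a test read only after the data were seen. The oxidative phosphorylation, NAD and biotin, and a mating type lists passed camera with a preset correlation without any single pair. Without replicate 1, 8 lists were shifted, and the iron, mitochondrial ribosomal protein, sulfur, sterol, G1/S and marker lists were lost. Without replicate 2, 8 were shifted, and the vitamin, amino acid, G1/S, cell wall and marker lists were lost. Without replicate 3, 13 were shifted, and the phosphate and cell wall lists were lost.

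Silencing of genes near chromosome ends is studied in histone tail mutants, and the share of such genes that rose was compared with that of other genes. Of 122 tested subtelomeric genes 2 rose, BNA6 and GDH3, and 6 fell, among them AAD4, IMD2 of guanine nucleotide synthesis (log2 -0.52, probe set may share signal), HSP31 and GTT2. The share that rose was 1.64%, against 0.863% of 4403 other genes (Fisher's exact test, two-sided, p = 0.293). The share that fell, a test chosen after the values were seen, was 4.92%, against 1.29% of the other genes (Fisher's exact test, two-sided, p = 0.00658, adjusted over both shares 0.0132). It was 10.1% without replicate 1 (exact p = 0.000603), but no longer passed without replicate 2 (0.84%, exact p = 0.365) or replicate 3 (0.775%, exact p = 0.159). The share that rose was 4.20% without replicate 1 (Fisher's exact p = 0.0558) and 0% without replicate 2 or replicate 3. Without the block, 0 of 122 were higher and 0 were lower (Fisher's exact p = 1 for each).

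None of the 16 chromosomes was shifted as a whole with all arrays included. The lowest adjusted p was that of chromosome II, 0.191 with the group only and 0.2 with the block, with a median log2 change of -0.01 over 306 genes.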

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

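The tests weighed here were chosen after the results were seen, except that of the splits with the group only. The tests of low-oxygen genes and of Sum1 targets were set before they were run, but address list shifts found in these same data. Control probe sets for ribosomal RNA, which no comparison used, stood above every wild-type array on mutant arrays 1 and 2. The 25S controls averaged 347 and 109 there against at most 73.4 in wild type, and the 18S controls 329 and 110.0 against at most 85.3. On mutant array 3 the 25S and 18S controls averaged 38.1 and 28.7, against 27.3 and 25.3 on wild-type array 3.

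The fall of HTB1 was weighed against a wrong label and against the position of its probe set. The lowest wild-type signal was 58.7 times the highest mutant signal, so no array lay at the level of the other group. This argues against an exchange of a wild-type and a mutant array. A swap of replicate numbers within a group would go unseen. Whether the probe set lies in the altered part cannot be told apart from a loss of the transcript, because 0 other probe sets are named for HTB1 alone. The signal of HTB2, the other H2B gene, was 4.3 in the mutant against 4.47 in wild type. As both are near background, HTB2 cannot show whether another H2B transcript takes the place of HTB1. A loss of the transcript is not shown by these values.

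The lower respiratory chain genes were set against the batch of replicate 3 and against ribosomal RNA on mutant array 1. The list's mean less that of the other genes was -0.16 in the pair with the smallest fall and -0.19 without replicate 1. Each lay more than 2 standard errors from 0, but these errors treat the list's genes as independent. The list's mean was also lower in the pairs of replicates 1 and 2 (-0.25 and -0.21), outside the batch of replicate 3. The shift thus does not rest on that batch alone. The list was chosen for its shift over these same 3 pairs, so a fall in each pair is a weak test of the batch. The 25S controls were higher in the mutant in each same-numbered pair (347 against 45.2, 109 against 73.4, 38.1 against 27.3). Leaving out replicate 1 therefore cannot exclude ribosomal RNA as a cause. A candidate explanation is a shift towards genes used at low oxygen. Of 7 further such genes none passed with the block. AAC3 was at log2 0.53, HEM13 at 0.46, HMG2 at 0.08 and SUT1 at 0.04. ERG11 was at -0.002, and OLE1 and FET4 were at -0.12. Their median was 0.04, against -0.06 for all genes, and lay at the 93.2 percentile of 10000 random lists matched on level. The bound set beforehand was the 95th percentile, so the explanation stays undecided.

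The higher NAD and biotin list was set against the same causes. Its mean less that of the other genes was 0.24 in the pair with the smallest rise and 0.25 without replicate 1. Each lay just over 2 standard errors from 0, and these errors treat its 17 genes as independent. Of the 17 genes 8 had a positive log2 change, so the mean rests on part of the list. The list's mean was also higher in the pairs of replicates 1 and 2 (0.24 and 0.25), outside the batch of replicate 3. The shift thus does not rest on that batch alone. This list too was chosen for its shift over these same pairs, so a rise in each pair is a weak test of the batch. Ribosomal RNA cannot be excluded, as its controls were higher in the mutant in each pair. A candidate explanation is lost repression by Sum1 and Hst1, which also hold down middle sporulation genes. The median of 15 such genes lay at the 94.8 percentile of random lists matched on level, below the bound of the 95th percentile set beforehand. As 0 of the 15 lay above the filter on dim genes, their values are near background and the question stays undecided.

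With the group only, 1 of 10 splits of the 6 arrays into 3 and 3 gave as many genes as the real one, which is the real split itself: it called 1 gene and the highest other 0. With the replicate block, 1 of the 4 splits that part all pairs did so, again the real one, with 103 genes against 0 for the highest other. The other 6 of the 10 splits put same-numbered arrays in 1 group. Both sets of splits are too few for a share under 0.05.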

How the results depend on the processing

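The alternatives within the fit with the replicate block, the batch block, replicates 1 and 2 alone and the test of subtelomeric falls were chosen after seeing the data. With the group only, the mitochondrial ribosomal protein list changed sign: its mean less that of the other genes was -0.10 with all arrays and -0.22 to 0.01 on leaving out each array, 0.01 without wild-type replicate 3 (0.00997, adjusted p = 0.89, over its alternatives 6.02e-05 to 0.991). No other list or named gene that had passed changed sign. Among genes and lists that had not passed some did on leaving out arrays, such as HHO1, CSE4 and HMRA1. In that fit, genes higher and lower (0 and 1) became 40 and 63 with the replicate block, 45 and 74 with the batch block, and 17 and 27 within replicates 1 and 2. At least 2-fold they became 4 higher with either block, and 5 higher and 2 lower within replicates 1 and 2. Quantile normalization gave 1 higher gene, also at least 2-fold, and leaving out each array gave 0 to 1 higher genes in both counts, the 1 without wild-type replicate 3. The shifted lists (13) became 0 with an estimated correlation and 0 with fry in its test of 1 direction, and 8 to 15 on leaving out each array, the 8 without mutant replicate 2. Chromosomes shifted were 0 to 1, the 1 without wild-type replicate 3. With the replicate block, the 40 higher and 63 lower genes became 86 and 95 with quantile normalization, 101 and 115 with median scaling, 22 and 39 with the filter at the 50th percentile, which tests fewer genes, 73 and 148 with a robust prior, and 16 and 11 over all probe sets. Without a trend in the prior 29 were lower. Leaving out a pair gave 7 to 79 higher and 6 to 153 lower. At least 2-fold, 4 higher and 1 lower became 7 and 2 with no filter on dim genes, 8 and 2 over all probe sets, 28 and 26 at a limit of 1.5-fold, and 2 lower with the smaller offset. Leaving out a pair gave 1 to 2 lower at least 2-fold. The 13 lists shifted with the block became 7 with median scaling, 8 to 13 on leaving out a pair, 0 with an estimated correlation and 0 with fry, and chromosomes shifted were 0 to 1, the 1 without replicate 1. Where no other reason is given, the cause was not tested. Of the 103 genes called with the block, 103 were also called with quantile normalization and with median scaling, 51 without a trend in the prior, 69 with no filter on dim genes, and 87, 27 and 12 without replicates 1, 2 and 3, where 102 of them were tested. The median log2 change of all genes was -0.06 as deposited, -0.03 with quantile normalization and -0.02 with median scaling. HTB1, TIR1, BNA4, BNA1, ANB1, COX26, RDN25-1, FLR1, AAD4 and YNL134C passed in each alternative with the block that tested them, and TIR1 had at most an adjusted p of 0.00725. Among values of named genes in the alternatives with the block, 106 lost and 42 gained their call, as did 35 and 4 of those of lists. The p of the share of subtelomeric genes that rose stayed above 0.05 in each alternative. The share that fell was 0% with the group only, and became 4.92% with the replicate block, 5.74% with the batch block and 2.33% within replicates 1 and 2, each past the threshold. On those same arrays of replicates 1 and 2, with the replicate block added, it was 0.775% and did not pass. From 4.92% with the replicate block it became 0.82% without a trend in the prior and 5.71% among the 5 outermost genes per arm, fewer genes, neither of which passed, and 0.775% to 10.1% on leaving out a pair, not passing without replicate 2 or 3. It passed at 9.02% with median scaling and with a robust prior, 2.34% with no filter on dim genes and 2.97% among the 20 outermost genes per arm. In camera with all arrays, the block changed no call of a list or chromosome. With fry in either direction, 16 lists passed with the block and 0 without it. Signal over background limits the dim genes, whose changes the offset shrinks.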

Other observations

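Several genes outside the fixed lists changed with the replicate block and were chosen after their values were seen. GAP1, the general amino acid permease, fell (215 ± 8.8 against 146 ± 36.4, n = 3, log2 -0.58, adjusted p = 0.0146), as did the ammonium transporter genes MEP2 (log2 -0.66, adjusted p = 0.0143) and MEP3 (-0.44, adjusted p = 0.0454), with groups that overlapped for MEP2 and MEP3. CAR2, of arginine breakdown, rose (log2 0.84, adjusted p = 0.000444), also with overlapping groups. Without the block none of these passed, and no list of nitrogen genes was tested.

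For some proteins, genes for a form used with oxygen and for another at low oxygen were both measured, and these pairs were picked after their values were seen. COX5A fell (log2 -0.42, adjusted p = 0.0314) while COX5B rose, and ANB1 rose while HYP2, its partner used with oxygen, was at -0.05 (adjusted p = 0.895). AAC3, the low-oxygen ADP/ATP carrier, was at 0.53 (adjusted p = 0.0708) and PET9, the main one, at -0.16 (adjusted p = 0.432). HMG1 and HMG2 were at 0.00 and 0.08, and neither passed. Whether the members of a pair differed was not tested.

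Small nuclear and nucleolar RNA genes included 3 of 39 that rose, SNR5, SNR14 and SNR50 (log2 0.48, 0.59 and 0.65), and 0 that fell, with a class median of 0.05. Among probe sets without a single gene, 0 of 1551 passed in a fit of their own with the block, while 4 of the 27 passing probe sets in the fit over all probe sets had no single gene, 3 higher and 1 lower.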
